A study of Amaranthus palmeri with 48 samples.

How the data were processed

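The series measured RNA in leaves of Palmer amaranth (Amaranthus palmeri), a broadleaf weed of field crops. Per the labels, the 48 libraries came from plants of a resistant and a susceptible phenotype, here called the resistant and the susceptible line, that were left untreated or sprayed with 1 of 5 herbicides. Per the series' design text, leaves were sampled 6 h after treatment. Per the labels, the work ran in 3 batches, each with its own untreated controls. Batch 1 held 2,4-D and mesotrione, batch 2 held atrazine and chlorsulfuron, and batch 3 held lactofen. Line, treatment and batch gave 16 groups of 3 libraries, and the titles number the plants. Plants 5, 7 and 8 of the resistant line and plants 5, 6 and 7 of the susceptible line appear in batches 1 and 2. Numbers 1, 4 and 8 of the resistant line and 3, 5 and 7 of the susceptible line appear in batch 3.

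Per the labels' protocols, total RNA was made into stranded polyA libraries and sequenced as read pairs. The submitters' processing notes name Trimmomatic, FastQC, STAR and DESeq2, with no role or version. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values are whole-number read counts per gene model, 1 column per library, with no scaling between libraries. Of the counts above 0, 99.1% were even, which is what counting both mates of each read pair gives, so a fragment usually adds 2 counts. Fragment counts (every count halved and rounded up) were run as an alternative. The table lists 26353 gene models, 24873 as mRNA and 1480 as tRNA, of which 23894 had a count in some library. A further line that names no gene held 0 counts and stayed out of totals and tests. Library totals ran from 16583010 to 72979429 counts. Reads shared between near-identical copies, overlapping genes or antisense partners could have been split by the counting, so values of such genes are uncertain.

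The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on the counts as deposited. It used TMM scaling factors, the default filter on low counts by group (20645 genes kept) and robust dispersion estimates. All 48 libraries entered 1 fit with a mean per group, which left 32 residual degrees of freedom. The square root of the common dispersion was 0.46. A gene was called when its Benjamini-Hochberg adjusted p over the 20645 genes was under 0.05. There were 19 comparisons. For each of the 5 herbicides, treated plants were compared with untreated plants of the same line and batch, in each line, and the difference between the responses of the 2 lines was tested as an interaction contrast. Untreated plants of the 2 lines were compared within each batch and over the mean of the 3 batches. CPM values use the TMM factors, and log2 values come from the fit with its standard error (SE). Where every library of a group had 0 counts, a lower bound of the fold is given against a floor of 3 counts in each library of that group, in place of a fitted fold. Where a group held a single fragment, the ratio has an exact 95% interval from the binomial distribution. Floors and that interval cover counting error only. The tests, groups, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to be later.

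The identifiers were not paired with gene names in the files used here, and no annotation was used. The gene lists fixed beforehand, which select genes by product name (detoxification families, hormone responses, photosynthesis, herbicide target pathways, cell types and others), could therefore not be applied, and their set tests are not reported here. The rule for named genes then gave, per comparison, at most 2 identifiers that rose and 2 that fell. These are the called genes with the largest log2 change whose group mean reached 5 CPM in the higher group. For a response or a line comparison, the libraries of the 2 groups also had to be apart in log2 CPM. The pooled line comparison asked for this within each batch only, so its libraries can overlap across batches. Genes outside this rule are said to be chosen after their values were seen.

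Same-numbered libraries were compared before the blocked fit was read, as the correlation of their deviations from the group means. It was 0.15 or more in every pair of 9 of the 10 treated and control pairs of groups, so there the numbers were taken to pair the libraries. The numbers come from the titles. In susceptible plants of batch 2 they do not give 3 clear pairs. After atrazine, different numbers correlated at up to 0.3 there, and same numbers at 0.33 or more. After chlorsulfuron the values were 0.43 and 0.22, and 2 of 3 libraries correlated best with their own number. In susceptible plants of batch 3 the lowest value for same numbers was -0.21, so there the numbers were not taken to pair the libraries. The fit with the plant number as a block was an alternative for every response. For the control plants pooled over batches, limma 3.58.1 (voom) with the plant number as a random block was the corresponding alternative, with an estimated correlation of 0.04. By the check of plant identity below, some of these blocks join different plants. Susceptible control 7 of batch 2 matched plant 6. Resistant control 8 and susceptible controls 5 and 7 of batch 3 matched the batch 1 plants of their numbers at only 80.2%, 73.3% and 69.8%. The 0.04 thus does not measure how alike libraries of 1 plant are. The labels say that plants were raised from seed, and do not say whether same-numbered libraries are leaves of 1 plant, clones or sister plants. By that check, batch 2 libraries other than the susceptible ones numbered 7 matched the batch 1 plant of their number at 93.1% or more. Different plants of batch 1 matched each other at no more than 81%. This argues against sister plants in batches 1 and 2, and leaves of 1 plant and clones cannot be told apart. The p-values thus measure the spread between these libraries.

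Plant identity was checked, after seeing the data, with genes that split the 6 plants of batch 1 into plants where the gene was on and plants where it was off in all 3 of their libraries. A stricter definition had given no such gene. A second one asked for a gap of at least 2 between the on and off libraries in log2(CPM + 0.5), and gave 116 genes. For each library of batch 2, the share of these genes whose on or off state matched each batch 1 plant was computed. The same was done in batch 3 with 531 genes chosen on its controls. These checks used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

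Alternatives planned beforehand were the size factors of DESeq2 within edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a fit of the batch or of the 18 control libraries alone, the blocks, an added 2-fold threshold and leaving out each library in turn. Added after seeing the data were fragment counts, total counts in place of TMM, and runs without libraries that stood apart. Overlaps between comparisons that share control libraries were set beside simulated unchanged groups. Controls of 3 libraries cannot be split into parts of 2. Other splits of the libraries were run for each comparison, all 10 where 3 stood against 3, and 100 drawn with a fixed seed for the differences between lines in response and for the pooled controls. For the former, treatment was first exchanged within a line. After those results were seen, a second scheme exchanged the lines within treated and within control libraries, and its values are the ones used unless both are given. It chose treated and control libraries separately, so its splits need not keep the libraries of a plant number together. The splits of the pooled controls were also run again with the susceptible control numbered 7 of batch 2 moving with plant 6, and without it.

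The steps were tested on simulated counts with the real means, library sizes and dispersions, in which 100 genes changed 2-fold and 100 changed 4-fold. The simulated lactofen response of the resistant line (3 against 3 libraries) recovered 31 and 58 of them, with 4 other genes called. The simulated difference between the lines' lactofen responses recovered 5 and 38, with 2 others. The simulated pooled comparison of controls recovered 67 and 81, with 6 others. Each ran on 20645 genes. A difference of 2-fold between the lines' responses was thus seldom detectable. The simulated libraries were drawn independently, with no plant repeated between batches. The recovery and other calls of the pooled comparison may therefore not hold for the real controls, which share plant numbers.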

Results

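Leaf RNA of Palmer amaranth was profiled 6 h after herbicide treatment in a resistant and a susceptible line, in 48 libraries that formed 16 groups of 3. The series addressed how plants that resist several herbicides, by breaking them down, differ in gene expression from plants that do not. The herbicides were 2,4-D, a synthetic auxin, and mesotrione, which blocks an enzyme needed for plastoquinone and tocopherol synthesis (batch 1, 18 libraries). Atrazine, which blocks electron transport at photosystem II, and chlorsulfuron, which blocks the synthesis of branched-chain amino acids, were in batch 2 (18 libraries). Lactofen, which blocks tetrapyrrole synthesis and lets a photosensitising porphyrin accumulate, was in batch 3 (12 libraries). Each batch had untreated controls of both lines. The libraries held 16583010 to 72979429 counts in batch 1, 44999718 to 62829178 in batch 2 and 41828563 to 59908233 in batch 3. Of the 26353 gene models in the table, 20645 passed the filter on low counts and were tested. Genes are given by the identifiers of the count table, which were not paired with names or coordinates.

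The first principal component of log2 CPM over the 2000 most variable genes held 45.8% of the variance and ordered the libraries by treatment. Lactofen libraries lay between 111.4 and 162.9 on it, chlorsulfuron libraries between 54.3 and 70.7, and atrazine libraries between 17.6 and 101.6. Libraries treated with 2,4-D lay between -38.6 and -14.9, mesotrione libraries between -71.8 and -23.1, and controls between -88.5 and -22.6. Within each treatment the 2 lines overlapped on it. The resistant control numbered 8 of batch 3 had the lowest TMM factor, 0.64, and its 10 most abundant genes took 12.1% of its counts, the highest share among the 48 libraries.

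**Figure D1:**
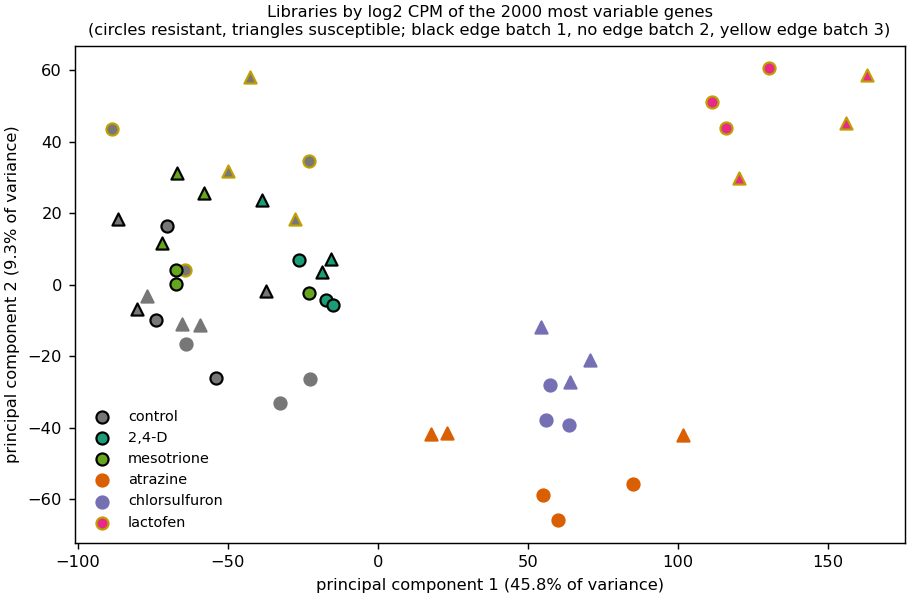
Each point is 1 of the 48 libraries, placed by its first 2 principal components of log2 CPM over the 2000 most variable genes (45.8% and 9.3% of the variance). Colour gives the treatment, shape the line and edge the batch, and lactofen libraries lie at 111.4 or more on the first component while no control lies above -22.6.

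Plant numbers recur across treatments and batches, and expression of 116 genes that told the 6 plants of batch 1 apart was read in batch 2. In 15 of the 18 libraries of batch 2 the on or off states matched the batch 1 plant of the same line and number best, at 93.1 to 100% of the genes. The susceptible libraries numbered 7 matched plant 6 at 100% (control), 97.4% (atrazine) and 94.8% (chlorsulfuron), and plant 7 at 54.3%, 55.2% and 52.6%. Libraries 6 and 7 of the same group still differed in their counts by more than sampling noise, with a chi-square per gene of at least 20.7 where noise gives about 1, so each was kept as a library. Susceptible groups of batch 2 therefore held 3 libraries whose patterns matched 2 plants of batch 1.

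**Figure D2:**
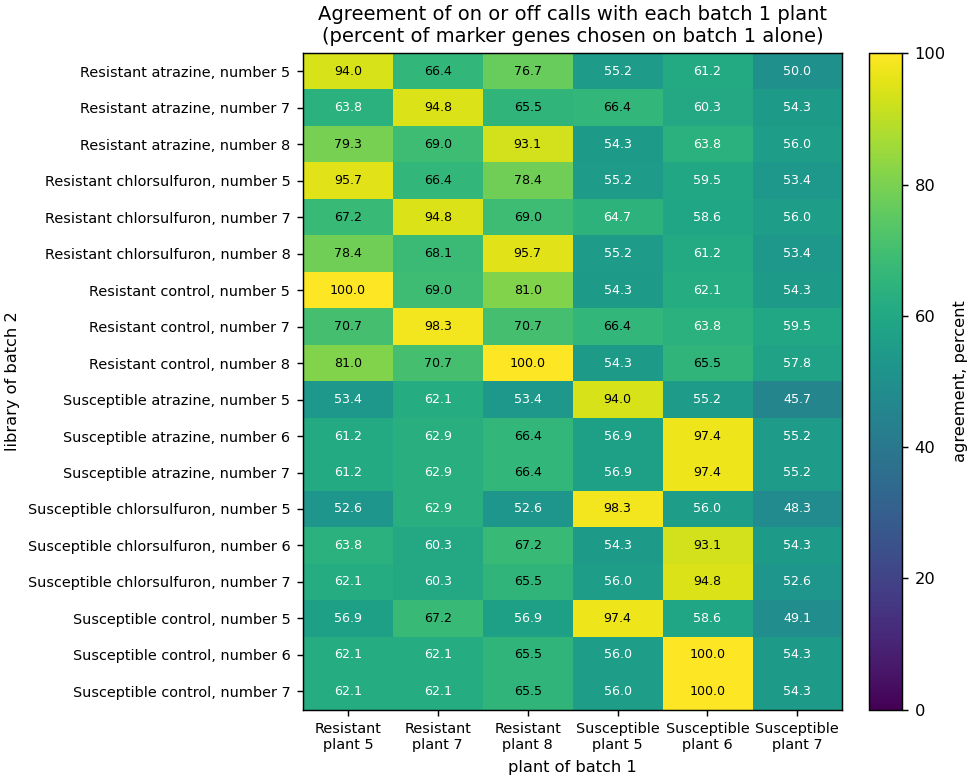
Each cell gives, for a library of batch 2 (vertical axis), the percent of the 116 marker genes whose on or off state matched that of a batch 1 plant (horizontal axis). The 3 susceptible libraries numbered 7 match plant 6 at 94.8 to 100% and plant 7 at 52.6 to 55.2%.

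2,4-D raised more genes than it lowered in both lines, except in resistant plants without control 5, where 567 genes were higher and 571 lower. In resistant plants AmaPaChr04Ag076890 rose from 0.143 ± 0.0867 to 42.1 ± 16.3 CPM (mean ± SD, n = 3; log2 change 7.98 ± 1.3 SE, edgeR adjusted p = 2e-04). AmaPaChr10Ag166430 rose in resistant plants from 1.27 ± 0.672 to 231 ± 117 CPM (log2 7.47 ± 1.16 SE) and in susceptible plants from 1.01 ± 0.0748 to 275 ± 135 CPM (log2 8.09 ± 1.18 SE). In susceptible plants AmaPaChr04Ag065490 rose from 3.98 ± 0.373 to 945 ± 755 CPM (log2 7.89 ± 1.1 SE, edgeR adjusted p = 8.8e-06), and AmaPaChr15Ag229200 fell from 19 ± 10.2 to 0.411 ± 0.157 CPM (log2 -5.51 ± 1.07 SE). In resistant plants AmaPaChr01Ag026280 fell from 11.7 ± 0.809 to 0.643 ± 0.365 CPM (log2 -4.18 ± 1 SE). AmaPaChr12Ag194890 was lower in both lines, with a log2 change of -4.65 ± 1.29 SE in resistant plants (adjusted p = 0.039) and -4.91 ± 1.3 SE in susceptible plants (adjusted p = 0.019). With the plant number as a block its edgeR value in resistant plants was -3.65 with an adjusted p of 0.066.

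After 2,4-D, 649 genes passed the threshold in resistant plants (475 higher, 174 lower) and 1089 in susceptible plants (740 higher, 349 lower). Of these, 382 were higher and 125 lower in both lines, where independent lists would share 17 and 3, and 0 changed in opposite directions. With the plant number as a block the counts were 1140 and 1983, and with total counts in place of TMM the share of higher genes went from 73.2% to 90.3% in resistant and from 68% to 81.6% in susceptible plants. The resistant count was 1138, 209 and 291 without control 5, 7 and 8, and 329, 334 and 345 without treated library 5, 7 and 8. The susceptible count was 643 and 436 without control 6 and 7, and 625 and 558 without treated library 5 and 6. Of the genes named, AmaPaChr12Ag194890 was no longer called without 4 of the 6 single libraries in resistant and 3 of 6 in susceptible plants, nor AmaPaChr01Ag026280 without 2 of 6.

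**Figure D3:**
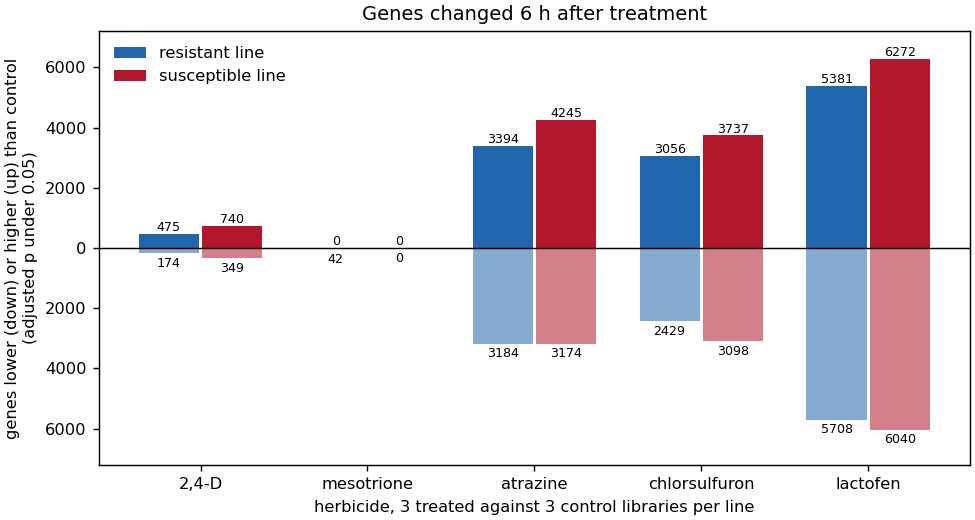
Bars give the number of genes higher (up) and lower (down) than in untreated plants of the same line and batch at an edgeR adjusted p under 0.05, for 3 treated against 3 control libraries. Lactofen changed 11089 genes in resistant and 12312 in susceptible plants, and mesotrione 42 and 0.

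Mesotrione changed few genes at 6 h, and edgeR called only lower genes, in resistant plants. AmaPaChr08Ag139070 fell from 44.3 ± 12.1 to 2.21 ± 0.956 CPM (log2 -4.33 ± 0.85 SE, edgeR adjusted p = 0.0097, n = 3), although it was no longer called without any 1 of 3 single libraries. AmaPaChr10Ag164470 fell from 89.9 ± 27.9 to 11.1 ± 2.7 CPM (log2 -3.02 ± 0.4 SE, adjusted p = 4e-05). In all, 42 genes were lower and 0 higher in resistant plants by edgeR, of 921 with an unadjusted p under 0.05, while DESeq2 called 114 (23 higher, 91 lower). The count was 24 without control 7, and 27, 27 and 23 without treated library 5, 7 and 8. In susceptible plants edgeR called 0 genes, with 756 at an unadjusted p under 0.05, and DESeq2 called 18 (5 higher, 13 lower). The 921 and 756 are under the share of 0.05 of the 20645 genes tested that exact p-values would give by chance. The test may thus have been strict here, so these numbers do not show that weak changes are absent. The 42 genes had a median log2 change of -2.53 after mesotrione in resistant plants and 0.41 in susceptible plants. Against the batch 2 controls of the resistant line the same mesotrione libraries were higher, at a median of 1.28, since the resistant controls of batch 1 stood above those of batch 2 by 3.58. The medians of the 42 genes were 3.03 to 3.65 log2 CPM in the resistant mesotrione libraries, and those of the other batch 1 libraries 4.23 to 5.97.

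Atrazine changed many genes in both directions. In resistant plants AmaPaChr10Ag171570 rose from 0.045 ± 0.0492 to 10.1 ± 12.6 CPM (log2 7.68 ± 1.65 SE, edgeR adjusted p = 0.00061, n = 3), and AmaPaChr13Ag209140 fell from 11.1 ± 12.7 to 0.146 ± 0.0411 CPM (log2 -6.24 ± 1.12 SE). In susceptible plants AmaPaChr12Ag195040 reached 8.34 ± 9.2 CPM, at least 165-fold above the floor of its controls, which had 0 counts. Its treated libraries ran from 2.52 to 18.9 CPM, so that bound leans on the highest library. AmaPaChr07Ag128190 reached 19.7 ± 30.6 CPM in susceptible plants against a single fragment in the controls, a ratio of 1970 with an exact 95% interval of 353 to 77700 that covers counting alone. Its treated libraries ran from 1.28 to 55.1 CPM, so 1 library carries most of that ratio. AmaPaChr12Ag194890, which also fell after 2,4-D, fell after atrazine in susceptible plants from 18.9 ± 12.3 to 0.171 ± 0.269 CPM (log2 -6.81 ± 1.45 SE). AmaPaChr14Ag221260 fell there from 38.2 ± 40.9 to 0.331 ± 0.308 CPM, but was not called without 2 of the 6 single libraries. Nor was it called without the 3 susceptible libraries numbered 7 of batch 2 (log2 -6.82, edgeR adjusted p = 0.052). In resistant plants AmaPaChr13Ag201780 rose by 6.73 ± 2.04 SE and AmaPaChr02Ag029950 changed by -6.14 ± 1.58 SE on the log2 scale, and each was lost without 1 of 6 libraries.

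After atrazine, 6578 genes were called in resistant plants (3394 higher, 3184 lower) and 7419 in susceptible plants (4245 higher, 3174 lower). Both lines shared 2845 higher and 2437 lower genes (698 and 490 for independent lists), and 1 gene changed in opposite directions. Asking also for a 2-fold change left 4365 genes in resistant plants. The susceptible count was 5510 (3201 higher, 2309 lower) without the 3 susceptible libraries numbered 7 of batch 2, below the resistant 6578. Those libraries matched a plant that the other susceptible libraries of their groups already held. With them left out the lines differ in their number of libraries, so the counts do not show which line responded more. The balance of directions depended on scaling, with 2828 higher and 3277 lower genes in resistant and 3428 higher and 3536 lower in susceptible plants when total counts replaced TMM. In resistant plants lower genes were also the more numerous with batch 2 alone in the fit (3523 higher, 3566 lower), a 2-fold change asked as well (2078, 2287) and without control 5 (2707, 2765).

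Chlorsulfuron also changed many genes in both directions. In resistant plants AmaPaChr04Ag065480 rose from 1.03 ± 0.111 to 261 ± 113 CPM (log2 7.98 ± 1.17 SE, edgeR adjusted p = 1.2e-05, n = 3). AmaPaChr09Ag149820 reached 8.11 ± 5.6 CPM in resistant plants against a single fragment in the controls, a ratio of 720 with an exact 95% interval of 129 to 28500 for counting alone, and its treated libraries ran from 3.95 to 14.5 CPM. AmaPaChr14Ag220820 fell from 241 ± 198 to 1.1 ± 0.73 CPM (log2 -7.78 ± 1.72 SE), and AmaPaChr02Ag035910 changed by -6.8 ± 1.67 SE but was not called without 1 of the 6 libraries. In susceptible plants AmaPaChr14Ag217290 reached 6.89 ± 1.53 CPM and AmaPaChr08Ag140480 5.87 ± 3.77 CPM, at least 136-fold and 116-fold above the floor of controls with 0 counts. AmaPaChr11Ag183560 fell there from 5.09 ± 2.09 to 0.064 ± 0.111 CPM (log2 -6.25 ± 1.61 SE), and AmaPaChr06Ag100380 from 5.63 ± 5.57 to 0.0324 ± 0.0312 CPM (log2 -7.32 ± 2.03 SE).

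After chlorsulfuron, 5485 genes were called in resistant plants (3056 higher, 2429 lower) and 6835 in susceptible plants (3737 higher, 3098 lower). The lines shared 2519 higher and 2027 lower genes (553 and 364 for independent lists), and 1 gene changed in opposite directions. With a 2-fold change asked as well the counts were 3427 (1579 higher, 1848 lower) and 4506 (2225 higher, 2281 lower), the resistant count without treated library 7 was 3417 (1701 higher, 1716 lower), and the susceptible count without the 3 libraries numbered 7 of batch 2 was 3516. With batch 2 alone in the fit, 2730 genes were higher and 3062 lower in resistant plants, and 3623 and 3630 in susceptible plants. In susceptible plants the median log2 change of all genes was 0.05 with TMM and 0.18 with total counts.

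Lactofen changed 53.7% of the genes tested in resistant and 59.6% in susceptible plants. In resistant plants AmaPaChr07Ag119940 reached 8.46 ± 4.98 CPM and AmaPaChr15Ag229910 5.92 ± 5.3 CPM (n = 3), at least 115-fold and 80.7-fold above the floor of controls with 0 counts. Treated libraries ran from 0.488 to 11.1 CPM for AmaPaChr15Ag229910. AmaPaChr01Ag005340 fell from 16.3 ± 10.7 to 0.0708 ± 0.0613 CPM (log2 -7.83 ± 1.26 SE, edgeR adjusted p = 2.9e-06), and AmaPaChr08Ag136150 from 12 ± 11.3 to 0.0715 ± 0.0831 CPM (log2 -7.37 ± 1.52 SE). In susceptible plants AmaPaChr09Ag159250 reached 6.83 ± 4.62 CPM and AmaPaChr11Ag179040 5.59 ± 3.84 CPM, at least 94.7-fold and 77.5-fold above the floor. AmaPaChr05Ag093810 fell there from 117 ± 202 to 0.411 ± 0.138 CPM and AmaPaChr12Ag194730 from 12.8 ± 21.8 to 0.0319 ± 0.0553 CPM, each with controls that differed widely, and they were no longer called without 1 and 4 of the 6 single libraries. Both were also lost with the plant number as a block (log2 -3.83 and -8.11, edgeR adjusted p = 0.13 and 0.072), although susceptible numbers do not pair the libraries of batch 3.

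After lactofen, 11089 genes were called in resistant plants (5381 higher, 5708 lower) and 12312 in susceptible plants (6272 higher, 6040 lower). The lines shared 4564 higher and 4768 lower genes (1635 and 1670 for independent lists), and 47 genes changed in opposite directions. A fit of batch 3 alone called 8531 and 9829 genes, a 2-fold change asked as well left 8580 and 9828, and without resistant control 1 the resistant count was 10045. The balance of directions depended on the setting. In resistant plants higher genes were the more numerous with the size factors of DESeq2 in edgeR (5741 higher, 5367 lower), no filter on low counts (5467, 5382), total counts (5386, 5329), batch 3 alone (4388, 4143) and DESeq2 (5919, 5616). In susceptible plants lower genes were the more numerous with a 2-fold change asked as well (4781 higher, 5047 lower) and without treated library 5 (6179, 6455).

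The responses of the 2 lines were then compared with each other, which asks whether resistant plants react differently to the same herbicide. For genes called in both lines, the mean log2 change in the called direction was computed per library. It was 2.1 ± 0.01 in resistant and 2.27 ± 0.1 in susceptible plants after 2,4-D (mean ± SD, n = 3), 1.74 ± 0.06 and 1.84 ± 0.35 after atrazine, 1.62 ± 0.13 and 1.84 ± 0.27 after chlorsulfuron, and 2.25 ± 0.08 and 2.44 ± 0.32 after lactofen. Exact two-sided permutation tests of 3 against 3 libraries gave p = 0.1, 1, 0.4 and 0.4 in that order, where 0.1 is the smallest p this design allows. Each library was set against the mean of its line's 3 controls, so the SD and the tests leave out the spread of the controls. For 2,4-D, resistant controls ran from -0.31 to 0.29 on this measure, while the lines differed by -0.17. The higher susceptible mean for atrazine rests on library 5, at 2.24, since libraries 6 and 7 (1.63 and 1.64) lay below all resistant libraries (1.7 to 1.81). For chlorsulfuron it rests on libraries 6 and 7 (1.98 and 2.01), with library 5 at 1.52 below all resistant libraries (1.53 to 1.76). For lactofen it rests on libraries 3 and 7 (2.52 and 2.72), with library 5 at 2.09 below all resistant libraries (2.16 to 2.31). After atrazine and chlorsulfuron, susceptible libraries 6 and 7 matched the same plant and correlated at 0.991, so the SD and the tests treat as separate plants 2 libraries that may not be. The same limit may hold for lactofen, where susceptible libraries 3 and 7 correlated at 0.973, and at 0.888 and 0.876 with library 5. The susceptible change was the larger of the 2 in 64.7%, 60.4%, 63.8% and 61.1% of those genes. Across genes, which are not independent replicates, the log2 changes of the lines correlated at r = 0.58, 0.79, 0.76 and 0.81, and at 0.08 for mesotrione.

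**Figure D4:**
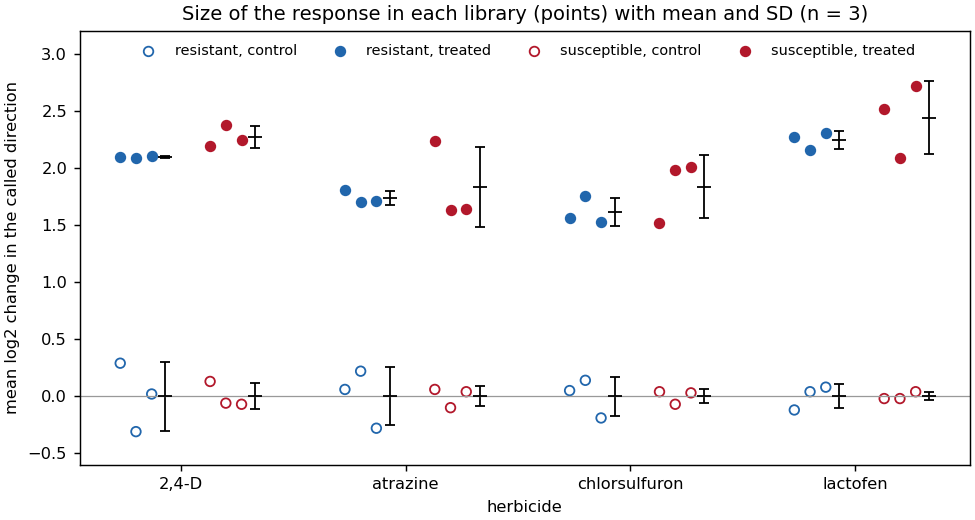
Points give the mean log2 change, in the called direction, of the genes called in both lines (507 for 2,4-D, 5282 for atrazine, 4546 for chlorsulfuron and 9332 for lactofen), for each treated (filled) and control (open) library, with mean and SD beside them (n = 3). Treated libraries lie between 1.52 and 2.72 and overlap between the lines for atrazine, chlorsulfuron and lactofen.

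Gene by gene, the response to lactofen differed between the lines for 467 genes by edgeR and 958 by DESeq2, but a fit of batch 3 alone called 7. AmaPaChr09Ag158260 reached 45.4 ± 37.3 CPM in resistant plants from 0.285 ± 0.378 CPM, and 0.0479 ± 0.0829 CPM in susceptible plants from 0.353 ± 0.0566 CPM (n = 3). AmaPaChr02Ag037090 reached 15.7 ± 14.8 CPM in resistant plants from 0.0631 ± 0.0598 CPM, and stood at 0.0812 ± 0.075 and 0.0979 ± 0.0581 CPM in treated and control susceptible plants. AmaPaChr13Ag205170 was at 48.9 ± 48.6 CPM in treated susceptible plants, 0.188 ± 0.212 CPM in their controls, and 0.187 ± 0.0306 CPM in treated resistant plants. AmaPaChr09Ag159250 was at 6.83 ± 4.62 CPM in treated susceptible and 0.244 ± 0.245 CPM in treated resistant plants. Of the 467 genes, 167 changed the same way in both lines, 128 of them more in susceptible plants. Another 107 rose and 59 fell in susceptible plants without passing the threshold in resistant plants, 53 rose and 36 fell in resistant plants without passing it in susceptible plants, and 45 went opposite ways. The 4 named genes were not called in the fit of batch 3 alone (adjusted p of 0.24, 0.26, 0.4 and 0.42), and were lost without 9, 2, 10 and 9 of the 12 single libraries in the order given. The count was 241 without resistant control 4, 214, 289 and 788 without resistant treated library 1, 4 and 8, 272 and 252 without susceptible control 5 and 7, and 142 and 2683 without susceptible treated library 3 and 5. With total counts in place of TMM it was 240, and the share of genes higher in the resistant response went from 48% to 61.2%. With the plant number as a block it was 1069, although susceptible numbers do not pair the libraries of batch 3. That block ended the calls of AmaPaChr09Ag159250 (-9.13, edgeR adjusted p = 0.055) and AmaPaChr13Ag205170 (-8.01, adjusted p = 0.057).

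For mesotrione the response differed for 26 genes, all with a lower value in the resistant response, and 25 of them were among the 42 that fell in resistant plants. AmaPaChr12Ag195780 went from 204 ± 164 to 22.7 ± 5.77 CPM in resistant and from 24.6 ± 15.9 to 77.5 ± 29.6 CPM in susceptible plants (difference of log2 changes -4.82 ± 1.01 SE, edgeR adjusted p = 0.025, n = 3), and was lost without 7 of the 12 single libraries. AmaPaChr01Ag006870 went from 108 ± 66.5 to 14.5 ± 3.31 CPM and from 24.2 ± 4.11 to 74.8 ± 20.5 CPM (-4.52 ± 0.82 SE, adjusted p = 0.0041). A fit of batch 1 alone called 1 gene and DESeq2 called 66. For atrazine the difference was called for 2 genes, AmaPaChr12Ag196560, which was at 30.3 ± 10.7 CPM in treated susceptible and 1.29 ± 0.261 CPM in treated resistant plants, and AmaPaChr02Ag042340, at 228 ± 14.2 and 106 ± 5.05 CPM, from controls at 49.4 ± 4 and 49.1 ± 2.76 CPM. Both were lost without the filter on low counts, with total counts, without the 3 susceptible libraries numbered 7 of batch 2, and without each of 10 of the 12 single libraries. With the plant number as a block, AmaPaChr12Ag196560 was at -5.02 with an edgeR adjusted p of 0.063 (from -5.13 ± 0.93 SE and 0.033). Without susceptible atrazine library 5 the count was 37, and DESeq2 called 56. For 2,4-D and chlorsulfuron edgeR called 0 genes, with 210 and 553 at an unadjusted p under 0.05, and DESeq2 called 13 and 29. The 210 and 553 are under the share of 0.05 of the 20645 genes tested that exact p-values would give by chance. The test may thus have been strict here, so these numbers do not show that weak differences are absent.

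Across herbicides, 176 genes were higher and 18 lower after 2,4-D, atrazine, chlorsulfuron and lactofen in both lines. Mesotrione, with 0 genes called in susceptible plants, was left out of this set. Independent lists of the same lengths would share 0.0012 and 1e-04. The 8 lists are not independent, since each herbicide enters for both lines and atrazine and chlorsulfuron share their controls, so an excess over these values was to be expected. AmaPaChr10Ag175360 rose in all 8 comparisons, by 4.82 to 7.62 on the log2 scale, and AmaPaChr11Ag183840 by 4.41 to 7.68. AmaPaChr13Ag205070 changed by -5.56 to -2.51, and AmaPaChr09Ag159990 by -4.04 to -2.1. These 4 genes, those with the largest smallest change, were chosen after their values were seen. Atrazine and chlorsulfuron had 1438 higher and 1462 lower genes in common in resistant plants (502 and 375 for independent lists) and 2131 and 1651 in susceptible plants (768 and 476). Their log2 changes correlated across genes at 0.65 and 0.72, with a covariance of 1.39 and 1.91. Unchanged groups simulated against the same controls gave a correlation of 0.5 in both lines, a covariance of 0.31 and 0.32, and overlaps of 0 or 1 gene. Compared directly, atrazine and chlorsulfuron libraries differed in 4520 genes in resistant and 5197 in susceptible plants.

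Untreated plants of the 2 lines were compared to find differences present before treatment. AmaPaChr14Ag217080 stood at 0.268 ± 0.171, 0.47 ± 0.152 and 0.354 ± 0.101 CPM in resistant controls of batches 1, 2 and 3, and at 23.7 ± 6.95, 16.6 ± 6.46 and 66.8 ± 47.7 CPM in susceptible controls (n = 3 each; log2 difference -6.37 ± 0.38 SE, edgeR adjusted p = 5.1e-14). AmaPaChr01Ag013770 was at 8.87 ± 8.28, 6.01 ± 6.16 and 4.82 ± 6.11 CPM in resistant and at most 0.0425 ± 0.049 CPM in susceptible controls (log2 7.56 ± 1.37 SE). AmaPaChr16Ag241890 was at 31.1 ± 49.6, 16 ± 15.3 and 35.5 ± 40.1 CPM in resistant and at most 0.43 ± 0.298 CPM in susceptible controls (log2 6.91 ± 1.23 SE). Neither was high in all resistant controls. In batches 1, 2 and 3 the lowest resistant control was at 0.113, 0.295 and 0.141 CPM for AmaPaChr01Ag013770. For AmaPaChr16Ag241890 it was at 0.226, 1.59 and 0.564 CPM. In the limma fit with the plant number as a block these 2 genes were not called, with log2 differences of 6.88 and 5.49 and adjusted p of 0.055 and 0.16. AmaPaChr10Ag169630 was lower in resistant controls (log2 -2.74 ± 0.74 SE, adjusted p = 0.035), but was lost without 10 of the 18 single libraries. AmaPaChr04Ag070180, chosen after its values were seen, was the 1 gene whose 24 resistant libraries (0.369 to 4.28 CPM) all lay above its 24 susceptible libraries (0 to 0.199 CPM), over all treatments.

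Over the 3 batches 629 genes differed between untreated plants of the lines (394 higher and 235 lower in resistant plants). That fit counts controls of batches 1 and 2 as independent libraries, although they share plant numbers. Within batches 1, 2 and 3 alone, 6, 23 and 34 genes were called, and 5 genes were called in at least 2 batches. A fit of each batch alone called 33, 98 and 2, and DESeq2 178, 212 and 290. The batch 1 count was 28 without resistant control 5, and 2 and 3 without susceptible control 5 and 7. The batch 2 count was 3 and 47 without resistant control 7 and 8, and 2, 2 and 3 without susceptible control 5, 6 and 7. The batch 3 count was 5 and 86 without resistant control 4 and 8, and 13 without susceptible control 7. The pooled count was 373 with the plant as a random block, 334 with the 18 control libraries alone in the fit, 376 with a 2-fold change asked as well and 353 without the susceptible libraries numbered 7 of batch 2. It was 401 without susceptible control 6 of batch 1, 401 and 384 without resistant control 5 and 7 of batch 2, and 409 and 398 without susceptible control 6 and 7 of batch 2. Across genes the line differences of batches 1 and 2, which share plant numbers, correlated at 0.53, and those of batch 3 with batches 1 and 2 at 0.26 and 0.24.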

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

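The tests of the libraries numbered 7 (except that of mixing), the leave-out test of mesotrione, both lactofen tests and the second set of splits of the line differences in response were chosen after the results were seen.

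In batch 2, the 3 susceptible libraries numbered 7 carry the on and off pattern of plant 6, while every other library of the batch matches its own number. Deposit of 1 library under both numbers is excluded, since libraries 6 and 7 of a group differ by a chi-square per gene of at least 20.7. A mixture of plants 6 and 7 is argued against by markers that are on in plant 7 and off in plant 6, which are at no higher level in libraries 7 than in libraries 6 (highest median difference 0.0 on the log2 scale). Material of plant 6, or of a genetically identical plant, that carried the number 7 remains a candidate explanation, with a match of at least 94.8% to plant 6. No biological explanation was tested.

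The response to mesotrione differed between the lines for 26 genes, and 42 genes fell in resistant plants. Among those of the 26 that reached 5 CPM in a group, AmaPaChr12Ag195780 (-4.82) and AmaPaChr01Ag006870 (-4.52) differed most. A single library does not account for the 42, as at least 23 were called with any 1 of the 6 left out, and of 100 splits that exchange the lines 3 gave as many as 26 genes (highest other 275, several times the real count, which points to a structure among the libraries, while exchanging the treatment within a line gave 4). These splits need not keep the libraries of a plant number together, so they do not settle whether chance gave the 26. Resistant controls of batch 1 that were high for the 42 genes might account for the fall, because the mesotrione libraries lay above the batch 2 controls by a median of 1.28. Resistant 2,4-D libraries of the same batch also lay below these controls in 38 of the 42 genes, which goes with high controls. Against high controls as the whole cause, their median change was only -0.87, where mesotrione gave -2.53. All batch 1 groups also stood above batch 2 for these genes. Resistant mesotrione libraries lay below susceptible ones by a median of -1.53 (resistant controls above susceptible ones by 1.35). The genes were chosen for this very difference, however. High controls and a response limited to resistant plants thus cannot be told apart without more controls of batch 1. A biological difference between the lines remains open and was not tested further.

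The response to lactofen differed between the lines for 467 genes, among them AmaPaChr09Ag158260 (10.15), AmaPaChr02Ag037090 (8.14), AmaPaChr09Ag159250 (-9.04) and AmaPaChr13Ag205170 (-8.61). The low scaling factor of resistant control 8 does not account for most of the count, which was 459 without that library, 317 of them among the 467. Scaling stays open for part of it, since total counts in place of TMM left 240 genes. A fit of batch 3 alone called 7 and none of these 4. Their log2 differences hardly moved in it (10.15, 8.13, -8.86 and -8.63 in the order given). Both fits take group means from the same libraries, so this was fixed by the design and does not support the 4 differences. That fit estimates the spread from batch 3 alone, so its lower count is not a test of scaling. Grouping by chance was not excluded, as 22 of 100 splits that exchange the lines gave as many genes (highest other 2804). Splits with several times the real count point to a structure among the libraries. These splits chose treated and control libraries separately, so differences between lines or plants can enter the difference in response. They thus do not decide whether chance gave the 467. When treatment was exchanged, 38 of 100 splits gave as many genes (highest other 13925). Those splits carry the lactofen response itself into the difference, so they say nothing about chance. Without susceptible treated library 5, 2683 genes were called, the other 2 treated libraries (r = 0.973, against 0.888 and 0.876 with library 5) may not be independent, and differences between single plants and a difference between the lines in their reaction to lactofen both stay open.

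The response to atrazine differed between the lines for 2 genes, AmaPaChr12Ag196560 (-5.13) and AmaPaChr02Ag042340 (-1.1), and 18 of 100 splits gave as many (highest other 1273), so chance could not be excluded for this count. Such splits need not keep the libraries of a plant number together, so they do not decide the question.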

How the results depend on the processing

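Fragment counts, total counts and runs without libraries that stood apart were chosen after seeing the data. No named gene turned its direction under the settings run, and the size factors of DESeq2 in edgeR and fragment counts left all 19 counts within 1.5 times. For the other settings, the counts that moved further follow, and the cause was not tested unless a threshold was added. DESeq2 called 1225 genes for 2,4-D in resistant and 1740 in susceptible plants, 13 for the difference of the lines' 2,4-D responses, 114, 18 and 66 likewise for mesotrione, and 56, 29 and 958 for the differences after atrazine, chlorsulfuron and lactofen. It called 1131 genes between the lines in controls, and 178, 212 and 290 in batches 1, 2 and 3. With only the libraries of the batch in the fit, the differences in response came to 1 gene for mesotrione, 6 for atrazine, 2 for chlorsulfuron and 7 for lactofen, and the line comparisons in batches 1, 2 and 3 to 33, 98 and 2. The main fit gave 6, 23 and 34 for these line comparisons, so the counts depend on which libraries share the estimate of the spread. The 18 control libraries alone gave 334 genes between the lines. With the plant number as a replicate block, 2,4-D changed 1140 genes in resistant and 1983 in susceptible plants, and the difference after lactofen, where susceptible numbers do not pair the libraries, came to 1069, while susceptible plants had 6546 higher and 6662 lower genes after lactofen. In limma with the plant number as a random replicate block, which joins some different plants, 373 genes differed between the lines. The block moved no other count by over 1.5 times. It ended the call of 6 named gene results, all of them lost elsewhere too when single libraries were left out. An added 2-fold threshold left 4365 genes for atrazine and 3427 for chlorsulfuron in resistant plants, 4506 for chlorsulfuron in susceptible plants, and 376 between the lines. Without the 3 susceptible libraries numbered 7 of batch 2, chlorsulfuron changed 3516 genes in susceptible plants, the lines differed in 353 genes and in 3 in batch 2, and the difference after atrazine came to 0. That difference was also 0 with no filter on low counts and with total counts, which gave 240 for lactofen.

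With each library left out in turn, counts ran from 209 to 1138 for 2,4-D in resistant and 436 to 892 in susceptible plants, 23 to 51 for mesotrione in resistant plants, 4587 to 6005 and 5780 to 6726 for atrazine, 3417 to 4612 and 4863 to 6837 for chlorsulfuron, and 10045 to 10425 and 11147 to 12634 for lactofen, resistant before susceptible. The differences in response ran from 22 to 27 for mesotrione, 0 to 37 for atrazine and 142 to 2683 for lactofen. The line differences ran from 384 to 610 over batches, 2 to 28 in batch 1, 2 to 47 in batch 2 and 5 to 86 in batch 3. Of such counts 50 moved by over 1.5 times and 106 did not. Of 372 such values of named genes, 283 stayed past the threshold and 89 did not, and 28 of the 46 results of named genes never lost their call. The set tests of gene lists (camera with an estimated correlation, fry) were not run, since the identifiers were not paired with names.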

Other observations

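The tests of neighbouring genes and of separate controls were chosen after the results were seen, as was the second set of splits of the line differences in response.

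The number of changed genes per herbicide exceeded what regrouping the same 6 libraries gave, except for mesotrione in susceptible plants. There are only 10 ways to part 6 libraries into 3 and 3, too few for a share under 0.05. Every other split mixes treated and control libraries, so a response itself raises the spread within its groups. The low counts of other splits are thus not a level of false calls, and only the rank of the real split is informative. The real split was the 1 split with as many genes for 2,4-D (649 genes in resistant plants against at most 2 in other splits, and 1089 against 0 in susceptible plants) and for mesotrione in resistant plants (42 against 3). It was likewise the 1 split for atrazine (6578 and 7419 against 0) and chlorsulfuron (5485 against 2, and 6835 against 1). The same held for lactofen (11089 against 575, and 12312 against 3074). Among the 4 splits that part all 3 pairs of plant numbers, where numbers were taken to pair the libraries, the highest others were 0 in resistant plants for 2,4-D, mesotrione, atrazine and chlorsulfuron and 202 for lactofen. In susceptible plants they were 0 for 2,4-D, mesotrione and atrazine and 1 for chlorsulfuron. Susceptible libraries 6 and 7 of batch 2 matched the same plant, so for atrazine and chlorsulfuron these are not 3 clear pairs. For mesotrione in susceptible plants edgeR called 0 genes (756 at an unadjusted p under 0.05, 18 by DESeq2), so all 10 splits necessarily gave as many, with at most 1. For the differences in response to 2,4-D and chlorsulfuron, 0 by edgeR (210 and 553 unadjusted, 13 and 29 by DESeq2), all 100 splits necessarily gave as many, with at most 277 and 702. Splits against a count of 0 say nothing about whether a response is present or differs. The unadjusted numbers given here are each under a share of 0.05 of the 20645 genes tested. Exact p-values would give that share by chance, so the test may have been strict here. Such numbers do not show whether a weak response or difference is present.

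Between the lines in untreated plants, 1 of 100 splits, the real one, gave as many as the pooled 629 genes (highest other 382). The real split is always 1 of the 100, so this argues against chance but cannot exclude it. It also does not settle the size of the count. Those splits move plants by number, and after this was seen they were run again with the susceptible control numbered 7 of batch 2 moving with plant 6, or left out. The real split was again the 1 of 100 with as many genes (629 against at most 382, and 397 against at most 215). Within batches the 10 splits are too few for a share under 0.05. The real split was the 1 split with as many genes in batch 1 (6 against 0) and batch 2 (23 against 0), and 1 of 3 in batch 3 (34 against 317).

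The 12 plants of the 2 lines may differ by line and not only plant by plant. If so, few other ways of parting the 12 plants would separate genes fully over all 48 libraries, and, with the susceptible libraries numbered 7 of batch 2 counted as plant 6, 11 of the 462 splits, the real one included, separated as many genes as the real split, which separated 1. The highest other split, with 12 genes, was that of batch 3 against the rest, so batch 3 stood apart in more genes than either line did.

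Genes that differ between the lines might lie together in the genome, as segments inherited together would. In the order of the identifiers, 43 pairs of neighbouring tested genes were among the 629, where random sets gave a mean of 19.1 and at most 36 (permutation p = 0.0001, the smallest that 10000 draws can give). Genes called after 2,4-D in resistant plants also lay together, with 50 pairs against 20.4, so neighbouring genes that respond together, or copies that share reads, could give the same pattern.

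Atrazine and chlorsulfuron changed many genes alike, and shared control libraries might account for that. With chlorsulfuron set against the batch 1 controls instead, the log2 changes still correlated across genes at 0.6 in resistant and 0.58 in susceptible plants, so the shared controls alone are excluded as the cause. The covariance exceeded the simulated one by 1.08 and 1.59. For 2,4-D and mesotrione, which share controls too, it differed from the simulated one by -0.01 and -0.06.

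In batch 3, the susceptible lactofen libraries numbered 3 and 7 had the same on or off state in 90% of 531 genes that told the controls apart, where other pairs of lactofen libraries reached at most 81.5%. Of the 6 lactofen libraries, 4 matched another control better than that of their own number. These were resistant 1 (63.7% for its own, 67.4% for control 4), susceptible 5 (58.4%, and 74.6% for control 7), and susceptible 3 and 7 (63.8% and 60.8%, and 64.4% and 65.7% for resistant control 8). Whether such genes change state after lactofen, or numbers were exchanged or plants repeated, was not tested. No plant of batch 3 matched a batch 1 plant at more than 85.3%. Untreated plants of batches 1 and 2 differed in 93 genes in the resistant and 77 in the susceptible line, although they carry the same numbers.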
